A study of Mus musculus with 90 samples.

How the data were processed

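Total RNA of 90 samples of pregnant mice was measured on a whole-transcript mouse array. The samples form 18 groups of 5 arrays: 3 maternal tissues at 5 gestational days and the placenta at 3. The deposited values are log2 signals that the authors made with RMA (background correction, quantile normalization and probe summary), per the labels' processing notes. The RMA version is not stated. The values ran from 1.64 to 14.45 with 0 missing. Array medians lay between 6.31 and 6.44 in liver, 6.59 and 6.66 in kidney, 6.82 and 6.90 in small intestine and 7.07 and 7.14 in placenta. Sorted values differed between arrays by 0.10 to 0.16 on average within a tissue and by 0.81 over all 90, so levels were compared within a tissue, and between tissues only to pick transcripts abundant in a tissue and near the floor in another.

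Of 35556 features, 21789 carried a single gene symbol, 1621 several and 12146 no listed gene. The single-symbol features stand for 19938 genes, and of the features of a symbol the one with the highest mean was kept. A gene was tested in a tissue when at least 5 of its arrays lay above the 30th percentile of the array, which left 14542 genes in liver, 14449 in kidney, 14507 in small intestine and 14421 in placenta.

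Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, gestational day as the factor), for 15 comparisons of days within tissues. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, from a two-sided moderated test. The 3 differences between maternal tissues in the gd19 change were interaction terms. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Of 53 lists of genes, those with at least 5 tested members in a tissue were tested: 31 in liver, 26 in kidney, 29 in small intestine and 32 in placenta. The list test was limma's camera with a preset correlation of 0.01, adjusted over the lists and comparisons of a tissue, and again with the correlation estimated per list. At gd19 a single list in liver (male-biased genes) and in kidney (circadian clock) held with an estimated correlation, and 0 in small intestine and placenta. Neither held that way once marker means were covariates, which also costs precision where a marker mean moves with the day.

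A group mean under the 30th percentile of its arrays (the dim level) was read as not above background, and the fold of such a gene is given as a lower bound against that level. This rule and the lists of other days under the added alternatives were computed after the values were seen. Genes were named by a rule. In the main comparison of a tissue (gd19 against gd0, or against gd10 in placenta), the 6 largest rises and 6 largest falls were taken among called genes for which all 5 arrays of a day lay above all 5 of the other, with predicted genes passed over. Up to 3 called members of each list with the largest change were added, 2 rises and 2 falls in each other comparison, and a fixed set of drug-handling genes whether or not they passed. Genes named for the differences between tissues were chosen after their values were seen. The tests, lists, this rule and 16 alternatives were set before the data were examined. Another 6 alternatives and 10 sets of marker genes of other tissues or cell types were added after the values were seen.

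The alternatives covered each array left out, array weights, other list tests (fry, estimated correlation), other filters, a plain two-sample test, a minimum change of 1.5-fold, median centring, quantile normalization, the replicate number as a block, other sets of arrays in the fit, the mean of the features of a symbol and an intensity trend in eBayes. The arrays of 8 samples whose titles end in an extra number were also left out together. The number of arrays limits the precision. The labels call the samples mice but do not state which arrays came from the same animal, so the p-values measure the spread between these samples. Tested on simulated data, with changes planted in 200 genes of each tissue, the fit recovered 98.5% of changes of 1 log2 unit in liver, 97.0% in kidney and in small intestine and 74.6% in placenta. For changes of 0.5 the shares were 89.6%, 91.0%, 61.2% and 34.3%. Each gene was drawn on its own, so arrays that stand apart and genes that move together were not simulated, and the shares may be too high. In the same simulation camera called a list of 20 unchanged genes in placenta (p under 0.05) and not in the other tissues. Features with several symbols or none were left out of the comparisons.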

Results

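RNA from 90 samples of pregnant mice was measured on a whole-transcript microarray that reads each gene with probes along its exons. Liver, kidney and small intestine of the mother were taken at gestational days (gd) 0, 7.5, 10, 15 and 19, and the placenta at gd10, 15 and 19, which makes 18 groups of 5 arrays. The labels call the samples pregnant mice at gd0 as well, and gd0 served as the reference for the maternal tissues. The study followed genes that metabolise and transport drugs over gestational age, and the comparisons below set each later day against gd0, or against gd10 in the placenta. The number of arrays limits the precision. Changes are log2 differences ± the standard error (SE) of the limma fit with n = 5 arrays per day, levels are means ± SD of the log2 values, and adjusted p-values are Benjamini-Hochberg values. A list count is given over all genes tested and again adjusted over the list alone.

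**Figure D1:**
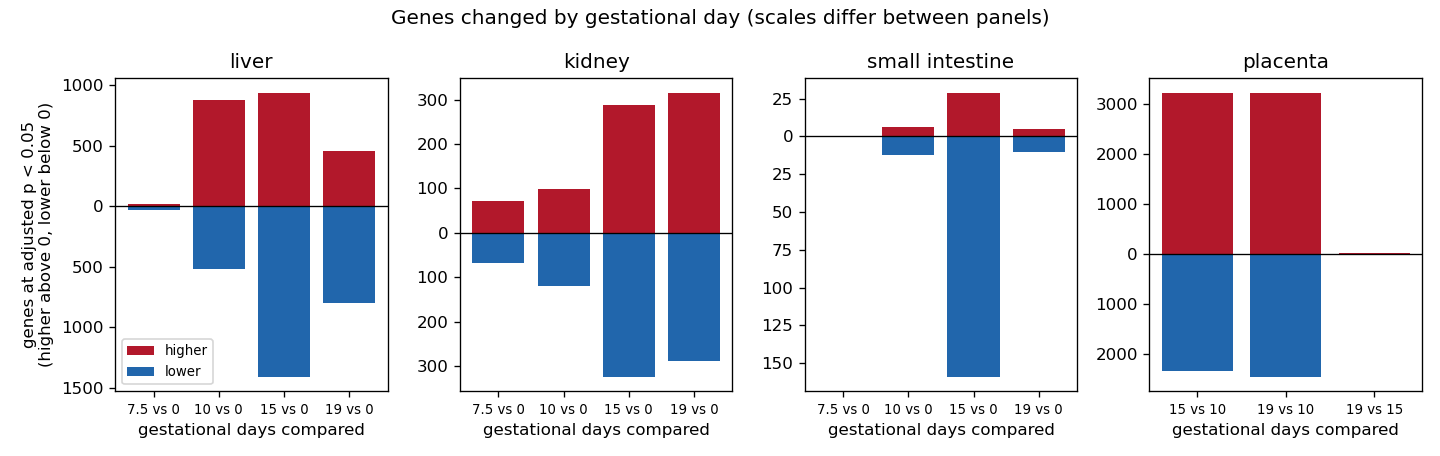
Number of genes higher (up) and lower (down) than the reference day in each comparison at an adjusted p under 0.05, with 1 panel per tissue and a different scale in each panel. Bars start at 0, and the counts run from 0 in the small intestine at gd7.5 to 5696 in the placenta between gd10 and gd19.

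In the liver at gd19, Cyp17a1, an enzyme of androgen synthesis, rose by 3.37 ± 0.33 (SE, n = 5), which is 10.4-fold (adjusted p = 2.18e-07), from 8.85 ± 0.67 to 12.22 ± 0.38. Gpx3, the secreted glutathione peroxidase, and Dnah11, an axonemal dynein, each rose 6.79-fold, by 2.76 ± 0.33 and 2.76 ± 0.23. Vnn1, a pantetheinase, rose by 2.38 ± 0.35, and the endogenous retroviral sequence Erv3 by 2.75 ± 0.29. Prl8a2, a prolactin-family gene best known from the decidua, was at least 7.56-fold higher (3.51 ± 0.40 from a gd0 signal below the dim level). Transcripts of trophoblast cells averaged 5.60 ± 1.26 on the gd19 liver arrays and 4.06 ± 0.08 at gd0, and the gd19 mean was also below the dim level (5.83). It was carried chiefly by replicate 4 (7.83), with the other gd19 arrays between 4.78 and 5.21. The fatty acid hydroxylase Cyp4a12a was at least 2.88-fold lower, with a change of -2.66 ± 0.21 (adjusted p = 1.07e-08) to a signal below the dim level of the gd19 arrays. Lower levels were also found for Hamp, the iron hormone hepcidin (-2.16 ± 0.44), for C9 of the complement system (-2.12 ± 0.18), for the receptor Adgrf1 (at least 1.998-fold lower, -1.95 ± 0.16 to a signal below the dim level), for the stearoyl-CoA desaturase Scd1 (-1.78 ± 0.14) and for the pseudogene Serpina4-ps1 (-2.80 ± 0.70). All 5 gd19 arrays lay beyond all 5 gd0 arrays for each of these 12 genes.

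**Figure D2:**
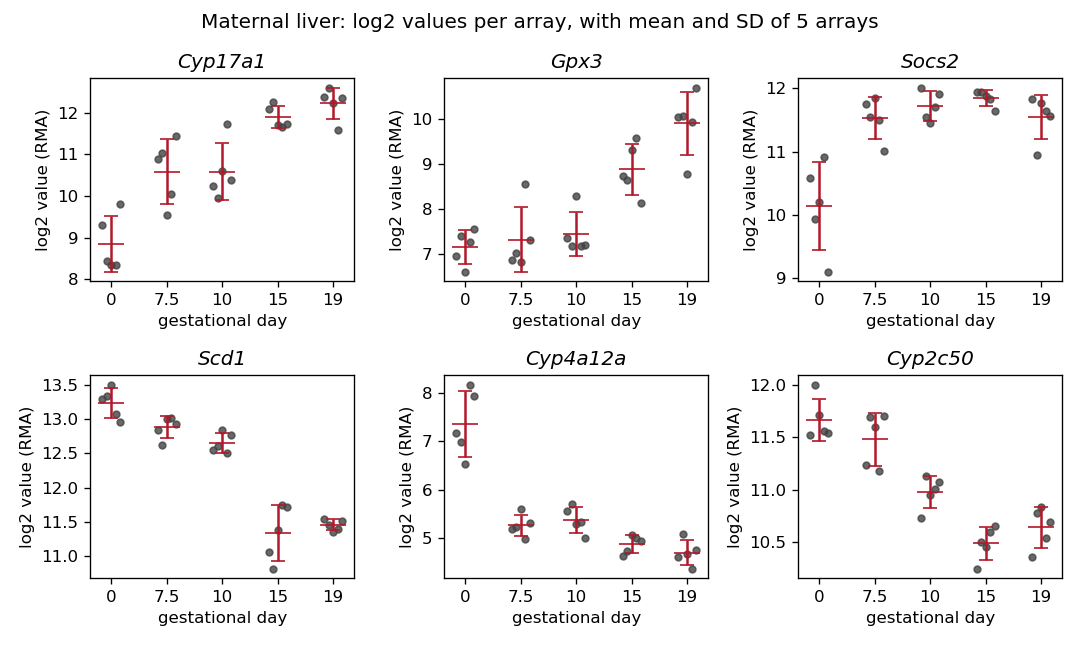
Log2 expression of Cyp17a1, Gpx3, Socs2, Scd1, Cyp4a12a and Cyp2c50 in liver by gestational day, with a point per array, the mean as a line and the SD of 5 arrays as the error bar. Cyp17a1 stood at 8.85 ± 0.67 at gd0 and 12.22 ± 0.38 at gd19, and Cyp4a12a at 7.36 ± 0.68 and 4.70 ± 0.26.

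Lists of lipogenesis, cholesterol and glucose metabolism shifted down in the gd19 liver, but none of them held with an estimated correlation. Of 22 measured lipogenesis genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone), with a median change of -0.64 (adjusted p = 1.74e-11; adjusted p = 0.133 with an estimated correlation). Scd1 was 3.43-fold lower, the malic enzyme Me1 2.59-fold lower (-1.37 ± 0.11) and the acetoacetyl-CoA synthetase Aacs 2.81-fold lower (-1.49 ± 0.29). Cholesterol synthesis and uptake showed 13 of 20 genes lower and 0 higher (14 lower adjusted over the list alone; median -0.41, adjusted p = 2.94e-11; adjusted p = 0.248 with an estimated correlation). Among them were Lss (-0.88 ± 0.15), Pmvk (-0.84 ± 0.15) and Hsd17b7 (-0.74 ± 0.10). Among 17 genes of glucose metabolism, 6 fell and 0 rose (9 lower adjusted over the list alone; adjusted p = 3.26e-06; adjusted p = 0.208 with an estimated correlation). They included the glucose-6-phosphatase G6pc (-1.39 ± 0.32), the glycogen phosphatase subunit Ppp1r3b (-0.98 ± 0.18) and the fructose kinase Khk (-0.71 ± 0.09). The fatty acid oxidation list had 1 member up, the pantetheinase Vnn1, and 2 down of 27 (1 and 2 adjusted over the list alone), and its list test did not pass (adjusted p = 0.111). Bile acid synthesis had 1 gene up and 3 down of 16 (3 and 6 adjusted over the list alone), among them Cyp39a1 (-1.16 ± 0.22) and Cyp27a1 (-0.61 ± 0.08).

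Lists of sex-biased genes and of growth hormone, prolactin and STAT5 signalling were tested in the same comparison. Of 19 genes that are more abundant in male than in female liver, 10 fell and 1 rose (10 and 2 adjusted over the list alone; median -0.29, adjusted p = 4.36e-06), among them Cyp4a12a, C9 and the steroid dehydrogenase Hsd3b5 (-1.58 ± 0.41). This call held with an estimated correlation (adjusted p = 0.0262), but not once the trophoblast mean was also a covariate (adjusted p = 0.0879 with an estimated correlation). The trophoblast mean ran from 4.78 to 7.83 at gd19 and up to 4.17 at gd0, so it nearly separates the days. A call lost with this covariate can therefore come from lost precision as well as from placental RNA. The female-biased list had 5 genes higher and 1 lower of 20 (6 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.0812). Its largest changes were Cyp17a1, Cux2 (0.71 ± 0.12), a repressor of male-biased genes, and Cyp2b13, which fell by 1.58 ± 0.19. In the growth hormone, prolactin and STAT5 list, 5 genes rose and 1 fell of 18 (5 and 1 adjusted over the list alone). The feedback inhibitors Socs2 and Cish rose by 1.41 ± 0.23 and 1.33 ± 0.26, and the receptor Lifr by 1.00 ± 0.09. The median of that list was -0.0008 while its mean was 0.22 and its test pointed up (adjusted p = 0.0356; adjusted p = 0.248 with an estimated correlation). Its call ended without liver gd0 replicate 3 (adjusted p = 0.0730), gd0 replicate 6 (0.0860), gd19 replicate 3 (0.0509) or gd19 replicate 4 (0.0931). Acute phase genes rose in 9 cases and fell in 1 of 26 (12 and 1 adjusted over the list alone; adjusted p = 4.05e-10; adjusted p = 0.322 with an estimated correlation). They were led by the metallothioneins Mt1 (1.27 ± 0.26) and Mt2 (0.86 ± 0.17).

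Drug-handling genes of the gd19 liver moved in both directions. Of 46 drug-metabolising cytochrome P450s, 10 fell and 4 rose (11 and 6 adjusted over the list alone), with Cyp2b13 2.98-fold and Cyp2c50 2.04-fold lower (-1.03 ± 0.12) and the median at -0.07 (adjusted p = 0.0193; adjusted p = 0.612 with an estimated correlation). Cyp3a11, a main drug oxidase, fell by 0.42 ± 0.11 (adjusted p = 0.0175), and Cyp2c37 fell by 0.44 ± 0.09. Cyp1a2 (0.01 ± 0.09, adjusted p = 0.941), Cyp2d22 (-0.02 ± 0.07, adjusted p = 0.900) and Cyp2e1 (-0.09 ± 0.05, adjusted p = 0.323) did not pass. Other drug-metabolising enzymes had 8 lower and 2 higher of 40 (12 and 2 adjusted over the list alone; adjusted p = 0.0274; adjusted p = 0.573 with an estimated correlation). Aldh1a7 was higher (1.66 ± 0.17) and Fmo5 lower (-0.78 ± 0.18). Glutathione transferases split 3 and 3 of 19 (4 and 7 adjusted over the list alone), with Gstp1 up by 1.03 ± 0.13, and 1 of 12 sulfotransferases, Sult3a2, rose (0.55 ± 0.11; 3 up and 2 down adjusted over the list alone). A single glucuronosyltransferase of 12, Ugt2b1, fell (1 also adjusted over the list alone). Uptake transporters had 4 lower and 1 higher of 34 (7 and 3 adjusted over the list alone), with Slc22a29 (-1.30 ± 0.19), Slc22a27 (-1.27 ± 0.15) and Slco1b2 (-0.26 ± 0.06) lower. The efflux pump Abcc3 fell by 1.44 ± 0.21, the 1 call among 21 efflux transporters (1 adjusted over the list alone). Slc10a1 (-0.16 ± 0.06, adjusted p = 0.0935) and Abcb11 (-0.20 ± 0.10, adjusted p = 0.207), which move bile acids in and out of hepatocytes, did not pass.

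The P450 call was lost without liver gd0 replicate 2 (adjusted p = 0.0756), gd0 replicate 6 (0.0645) or gd19 replicate 4 (0.0595), the array with most trophoblast signal, and the Cyp3a11 call without gd19 replicate 4 (adjusted p = 0.0592). The call of the other enzymes ended without gd0 replicate 2 (adjusted p = 0.0756) or gd0 replicate 6 (0.0673). The efflux list passed narrowly (adjusted p = 0.0491; adjusted p = 0.450 with an estimated correlation) and lost its call without any of 11 arrays, at most at adjusted p = 0.107. Of the remaining liver lists, nuclear receptors had 7 lower and 1 higher of 35 (8 and 1 adjusted over the list alone; Nr0b2 -1.07 ± 0.31, Foxa3 0.90 ± 0.18) without a list call (adjusted p = 0.103). Adipose markers had 2 of 7 lower (4 adjusted over the list alone; adjusted p = 0.0136; adjusted p = 0.289 with an estimated correlation; 0.0604 without gd0 replicate 6). Cell cycle genes passed as a list upward (adjusted p = 0.0364; adjusted p = 0.795 with an estimated correlation) with 0 of 47 called singly by limma (0 adjusted over the list alone). That call ended without gd0 replicate 5 (0.0597), gd0 replicate 6 (0.123), gd19 replicate 3 (0.305) or gd19 replicate 4 (0.0718). Iron handling had 3 up and 3 down of 22 (5 and 3 adjusted over the list alone), and the renin-angiotensin-aldosterone list 4 and 2 of 18 (7 and 2). Extracellular matrix had 1 and 4 of 23 (2 and 5) and endoplasmic reticulum stress 2 and 0 of 23 (2 and 1). None of these 4 passed as a list. The circadian list had 1 gene up of 17, Bhlhe41 (at least 1.20-fold, 1.31 ± 0.20 from a signal below the dim level; 1 up and 4 down adjusted over the list alone), and interferon-stimulated genes had 1 down of 21 (4 adjusted over the list alone). Macrophage markers had 1 up and 1 down of 14 (2 and 1 adjusted over the list alone). Immediate early genes had 2 down of 17, erythroid markers 1 down of 6, and B, plasma and T cell markers 1 down of 10, with the same counts adjusted over the list alone, while 0 neutrophil and 0 smooth muscle markers were called either way.

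In total 1250 of 14542 genes differed between gd19 and gd0 in the liver, 453 higher and 797 lower, and 293 of them by at least 1.5-fold. Over all genes tested, called or not, all 5 arrays of a day lay above all 5 of the other for 1071 (7.36%), where a random split of 10 arrays separates 0.794%. The share of higher genes, 36.2%, moved to 50.1% after a further quantile normalization and to 48.4% with each array centred on its median. The count was 825 without gd19 replicate 6, 510 with a plain two-sample test, 829 with all 90 arrays in the fit and 375 with the trophoblast mean as a covariate. That covariate nearly separates gd19 from gd0, so the lower count can also come from lost precision.

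Earlier in gestation the liver count was 51 at gd7.5 (18 higher and 33 lower, but 171 and 85 with all 90 arrays in the fit), 1391 at gd10 (876 and 515) and 2345 at gd15 (939 and 1406). At gd7.5 Cish (1.56 ± 0.26) and Socs2 (1.39 ± 0.23) rose, while Cyp4a12a (at least 3.02-fold lower, -2.10 ± 0.21 to a signal below the dim level) and the hepcidin paralog Hamp2 (-1.52 ± 0.25) fell. Cell cycle genes shifted up as a list at gd7.5 (median 0.70, adjusted p = 2.21e-27), with 0 of 47 passing limma over all genes and 37 adjusted over the list alone, and adjusted p = 0.244 with an estimated correlation. At gd10 the acute phase proteins Saa1 (at least 6.32-fold, 2.67 ± 0.70 from a signal below the dim level) and Saa2 (2.59 ± 0.62) rose, and Rgs16 (-2.51 ± 0.41) and the phosphatidate phosphatase Lpin1 (-2.32 ± 0.40) fell. Macrophage markers rose in 13 of 14 cases at gd10 (13 adjusted over the list alone; adjusted p = 9.14e-14; adjusted p = 0.133 with an estimated correlation). Interferon-stimulated genes rose in 12 of 21 (14 adjusted over the list alone; adjusted p = 2.94e-11; adjusted p = 0.208 with an estimated correlation). At gd15 Dnah11 was 16.4-fold and the co-chaperone Dnajc12 10.8-fold higher, and Rgs16 was 8.75-fold lower. Of 46 P450s, 16 fell at gd15 while 5 rose (20 and 6 adjusted over the list alone; adjusted p = 0.00101; adjusted p = 0.488 with an estimated correlation). Uptake transporters at gd15 had 12 lower and 3 higher of 34 (13 and 3 adjusted over the list alone; adjusted p = 0.0163; adjusted p = 0.248 with an estimated correlation).

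The gd7.5 count ran from 16 without liver gd0 replicate 2 to 490 without gd7.5 replicate 2, and was 0 with a plain two-sample test (2018 genes in limma below an unadjusted p of 0.05). The gd10 count ran from 711 without gd10 replicate 2 to 2103 without gd0 replicate 1. At gd10 the share of higher genes moved from 63.0% to 34.1% with each array centred on its median and to 53.8% after quantile normalization.

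In the kidney at gd19, Hdc, which makes histamine from histidine, rose 6.47-fold, by 2.69 ± 0.38 (SE, n = 5; adjusted p = 0.000671). Complement component C7 rose by 1.55 ± 0.20, Socs2 by 0.99 ± 0.13, the transcription factor Foxq1 by 0.98 ± 0.21 and the immunoglobulin joining chain Jchain at least 1.41-fold (1.06 ± 0.27 from a signal below the dim level). Albumin (Alb), a hepatocyte product, rose by 2.73 ± 0.66, and the mean of 14 hepatocyte transcripts on the kidney arrays was 8.19 ± 1.55 at gd19 and 8.44 ± 2.51 at gd10 against 6.31 ± 0.14 at gd0. Lower levels were found for Gadd45g, a stress response gene (-1.49 ± 0.24), the steroid dehydrogenase Akr1c14 (-1.64 ± 0.45), and the carboxylesterase Ces1f (-1.48 ± 0.41). The same held for the amino acid aminotransferase Bcat1 (-1.47 ± 0.39), the amino acid carrier Slc6a15 (-1.44 ± 0.34) and Rnf24 (-1.52 ± 0.40).

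**Figure D3:**
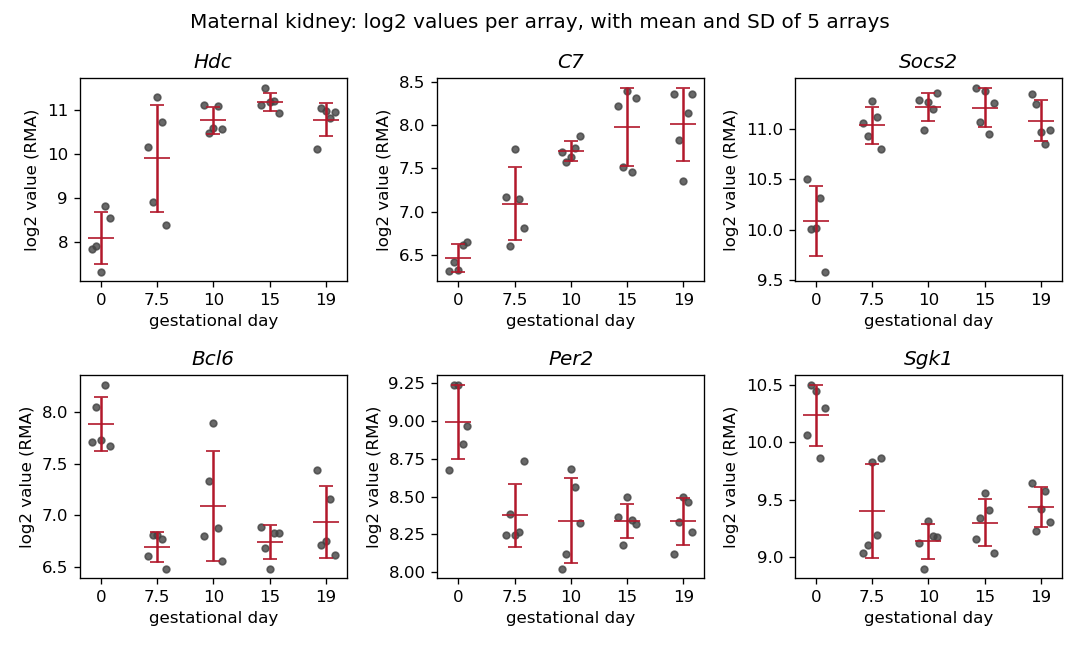
Log2 expression of Hdc, C7, Socs2, Bcl6, Per2 and Sgk1 in kidney by gestational day, with a point per array, the mean as a line and the SD of 5 arrays as the error bar. Hdc stood at 8.08 ± 0.59 at gd0 and 10.77 ± 0.38 at gd19, and Per2 at 8.99 ± 0.25 and 8.34 ± 0.15.

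Clock genes fell in the gd19 kidney. Of 17 circadian genes 6 fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.000301), and the call held with an estimated correlation (adjusted p = 0.0313). It did not hold that way without the 3 arrays high in liver transcripts (0.0832) or with the hepatocyte and adipose covariates (0.0690), while the preset correlation called it in both (0.000137 and 0.000214). The clock repressor Per2 fell by 0.66 ± 0.12, the clock-controlled protease Usp2 by 0.55 ± 0.08 and Ciart by 1.06 ± 0.30. Fatty acid oxidation genes rose in 8 of 26 cases and fell in 0 (12 and 1 adjusted over the list alone; median 0.20, adjusted p = 7.03e-08; adjusted p = 0.232 with an estimated correlation). The members that rose included the pantetheinase Vnn1 (0.85 ± 0.16), the thiolase Acaa2 (0.53 ± 0.09) and the thioesterase Acot2 (0.61 ± 0.15). Glucose metabolism had 4 of 17 genes higher (5 adjusted over the list alone; adjusted p = 0.00157; adjusted p = 0.187 with an estimated correlation), among them Fbp1 of gluconeogenesis (0.30 ± 0.07). Renal salt and water transport had 4 of 35 lower and 1 higher (6 and 1 adjusted over the list alone) without a list call (adjusted p = 0.128). The aldosterone-induced kinase Sgk1 fell by 0.80 ± 0.15 and the loop carrier Slc12a1 by 0.59 ± 0.14. The calcium channel Trpv5 and the calcium-binding S100g, both of distal tubule calcium uptake, rose by 0.35 ± 0.10 and 0.35 ± 0.08, 2 of 24 genes of calcium and phosphate handling (3 up and 2 down adjusted over the list alone).

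Among drug-handling genes of the kidney, 5 of 32 P450s rose and 1 fell (9 and 1 adjusted over the list alone; median 0.29, adjusted p = 8.35e-06; adjusted p = 0.371 with an estimated correlation). Cyp2d12 rose by 0.67 ± 0.11 and Cyp4b1 by 0.47 ± 0.11, while Cyp2d9 was lower (-0.56 ± 0.15). The median of this list was 0.02 with hepatocyte and adipose marker means as covariates (adjusted p = 0.718, the highest of its alternatives, which went down to 4.44e-08). Glutathione transferases passed upward as a list (adjusted p = 0.00500; adjusted p = 0.371 with an estimated correlation) with 0 of 19 called singly (0 adjusted over the list alone). That call also ended with the covariates, as 1 of 3 kidney lists that lost their call there without a turned direction. The others of these 3 are among the glucose, macrophage, cell cycle and extracellular matrix lists. Of 33 other enzymes 3 carboxylesterases fell, Ces1f, Ces1e (-0.83 ± 0.15) and Ces1d (-0.65 ± 0.18), and 0 rose (3 and 0 adjusted over the list alone). Uptake transporters had 4 higher and 2 lower of 34 (5 and 9 adjusted over the list alone), led by the monocarboxylate carrier Slc16a1 (0.93 ± 0.20) and Slc22a29 (0.65 ± 0.12). The efflux pump Abcb1a fell by 0.49 ± 0.11 (adjusted p = 0.0114), 1 of 2 efflux transporters lower of 17 (2 down and 1 up adjusted over the list alone). The organic ion transporters Slc22a2 (adjusted p = 0.985), Slc22a6 (0.18 ± 0.09, adjusted p = 0.266), Slc22a8 (0.15 ± 0.07, adjusted p = 0.206) and Slc47a1 (0.01 ± 0.06, adjusted p = 0.945) did not pass. The pump Abcg2 did not pass either (0.17 ± 0.05, adjusted p = 0.0591).

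Of the other kidney lists, macrophage markers had 2 of 9 higher (4 adjusted over the list alone; adjusted p = 0.00155; adjusted p = 0.398 with an estimated correlation), with Adgre1 up by 0.72 ± 0.13. Cell cycle genes had 2 of 31 higher (4 adjusted over the list alone; adjusted p = 0.000914; adjusted p = 0.469 with an estimated correlation), with Mcm7 up by 0.34 ± 0.05. Extracellular matrix shifted down (adjusted p = 0.00976; adjusted p = 0.649 with an estimated correlation) with 0 of 24 called by limma (0 adjusted over the list alone). Nuclear receptors had 1 up and 1 down of 33 (1 and 3 adjusted over the list alone) and immediate early genes 2 down of 17 (3 adjusted over the list alone). The renin-angiotensin-aldosterone, B, plasma and T cell, and adipose lists had 1 up each (2 up and 1 down, 1 and 1, and 1 up adjusted over the list alone). Kidney segment markers had 1 down, Slc12a1 (1 adjusted over the list alone). No gene passed in the cholesterol, interferon, injury, glucuronosyltransferase, sulfotransferase, erythroid and smooth muscle lists, and adjusted over the list alone only 1 injury marker rose.

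In total 604 of 14449 kidney genes differed at gd19, 316 higher and 288 lower, 79 of them by at least 1.5-fold. Over all genes tested the arrays of the 2 days did not overlap for 1196 (8.28%; 0.794% by chance). The count was 217 without kidney gd0 replicate 2, 703 without gd10 replicate 1, 327 with a plain two-sample test, 230 with the hepatocyte and adipose covariates and 149 with all 90 arrays in the fit. Of 46 called genes named for this comparison, 28 lost the call without some array, most often gd0 replicate 2 (25 genes), and Akr1c14, Ces1f, Bcat1, Rnf24, Slc6a15, Alb, Jchain, Ciart, Trpv5 and Slc12a1 were among them. The share of higher genes moved from 52.3% to 38.8% with each array centred on its median.

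At gd7.5 139 kidney genes differed (71 higher, 68 lower), at gd10 217 (98 and 119) and at gd15 611 (287 and 324). Trophoblast transcripts on the gd7.5 kidney arrays averaged 4.57 ± 0.45 and reached 5.22, against 4.04 ± 0.04 at gd0, all below the dim level of the arrays, and no fit of the gd7.5 changes took them into account. At gd7.5 Foxq1 (1.11 ± 0.21) and Cish (0.97 ± 0.15) rose, and the phosphatase Dusp1 (-1.26 ± 0.18) and the repressor Bcl6 (-1.19 ± 0.19) fell. Hdc stood 6.40-fold above gd0 at gd10 and 8.57-fold above it at gd15. At gd10 Cyp4f14 rose by 1.26 ± 0.32, and Nat8f5 (-1.39 ± 0.22) and the kinase Plk3 (-1.11 ± 0.22) fell. Several lists passed at gd10 both ways of setting the correlation. These were cholesterol synthesis, with 6 of 20 genes higher (13 adjusted over the list alone; adjusted p = 0.0212 with an estimated correlation), and interferon-stimulated genes, with 2 of 20 higher (13 adjusted over the list alone; 0.0376). Macrophage markers followed with 3 of 9 higher (8 adjusted over the list alone; 0.0313). Injury markers passed too with 0 of 11 genes called singly by limma (0 adjusted over the list alone; 0.0320). Of the 5 gd10 arrays, replicates 3 and 6 carried hepatocyte transcripts at 11.67 and 10.64, against a mean of 6.31 at gd0, and replicate 4 adipose markers at 10.79. Without the 3 kidney arrays highest in liver transcripts, these 2 among them, the gd10 count was 93, and with the covariates 119. With an estimated correlation cholesterol synthesis was then at adjusted p = 0.0832 and 0.0690, interferon at 0.151 and 0.115, macrophage markers at 0.0954 and 0.125, and injury markers at 0.151 and 0.482. The preset correlation called each of these lists both ways, except injury markers with the covariates (adjusted p = 0.113). Circadian genes fell at gd7.5 (2 of 17; 7 adjusted over the list alone), gd10 (6; 9 adjusted over the list alone) and gd15 (6; 8 adjusted over the list alone), with adjusted p = 0.0212, 0.0268 and 0.0313 with an estimated correlation. With an estimated correlation the adjusted p was above 0.05 without the 3 arrays (0.0832, 0.0832 and 0.0843) and with the covariates (0.0616, 0.0616 and 0.0690), so those calls rest on the preset correlation. At gd15 Igf2 rose by 1.88 ± 0.50, and Akr1c14 (-1.56 ± 0.45) and Ces1f (-1.55 ± 0.41) fell. The gd7.5 count was 48 without kidney gd0 replicate 3, 252 without gd7.5 replicate 2 and 0 with a plain two-sample test (1971 genes below an unadjusted p of 0.05). The gd10 count was 98 without gd0 replicate 6 and the gd15 count 321 without gd0 replicate 6.

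In the small intestine at gd19 few genes passed. Slc31a1, the copper importer, rose by 0.61 ± 0.09 (SE, n = 5), which is 1.52-fold (adjusted p = 0.0104), and the mitochondrial carrier Slc25a43 by 0.89 ± 0.14, which is 1.85-fold. H2-Eb1 of the class II major histocompatibility complex (MHC) rose by 0.58 ± 0.11 and Cish by 0.55 ± 0.11. The heat shock protein Hsph1 fell by 1.27 ± 0.23 and the receptor Gpr17 by 0.71 ± 0.14, with smaller falls of Zfp608 (-0.48 ± 0.09), Arhgef38 (-0.47 ± 0.09), the potassium channel Kcnn3 (-0.44 ± 0.08) and the ubiquitin ligase Lnx1 (-0.41 ± 0.08). For drug handling, the oxidases Cyp3a11 (0.47 ± 0.59) and Cyp3a13 (-0.14 ± 0.20), and the efflux pumps Abcb1a (-0.26 ± 0.24), Abcg2 (-0.06 ± 0.25) and Abcc2 (-0.27 ± 0.27) did not pass. The uptake carriers Slc15a1 (0.03 ± 0.10) and Slco2b1 (-0.08 ± 0.10) did not pass either, and the adjusted p-values of these 7 genes lay between 0.795 and 0.959. Slc10a2, the bile acid carrier of the distal ileum, stood at 7.25 ± 2.68 at gd19 and 9.31 ± 2.10 at gd0 (adjusted p = 0.697), and the mean of distal intestine transcripts at 8.70 ± 1.36 and 9.69 ± 1.32.

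Of the 29 intestinal lists, 10 passed at gd19 and 0 held with an estimated correlation. MHC class II had 1 of 7 genes higher (6 adjusted over the list alone; median 0.32, adjusted p = 1.03e-06; adjusted p = 0.166 with an estimated correlation). B, plasma and T cell markers shifted up (median 0.52, adjusted p = 1.24e-05; adjusted p = 0.552 with an estimated correlation) with 0 of 15 called singly (0 adjusted over the list alone). Circadian genes shifted down (median -0.37, adjusted p = 8.74e-06; adjusted p = 0.241 with an estimated correlation), with 0 of 16 over all genes and 7 adjusted over the list alone. Nuclear receptors shifted down as well (adjusted p = 0.000390; adjusted p = 0.166 with an estimated correlation; 3 of 34 adjusted over the list alone). Downward shifts with 0 genes called over all genes, and 2 lower in each list adjusted over the list alone, were found for a further 3 lists. These were glucuronosyltransferases (adjusted p = 0.00560; adjusted p = 0.552 with an estimated correlation), immediate early genes (0.00570; adjusted p = 0.552 with an estimated correlation) and stem cell markers (0.00308; adjusted p = 0.291 with an estimated correlation). Exocrine pancreas markers, which belong to another organ, were lower (median -1.11, adjusted p = 0.00127; adjusted p = 0.570 with an estimated correlation) with 0 of 11 called (0 adjusted over the list alone), and this call ended without small intestine gd0 replicate 1 (adjusted p = 0.171). P450s (adjusted p = 0.0246; adjusted p = 0.788 with an estimated correlation) and cell cycle genes (adjusted p = 0.00111; adjusted p = 0.789 with an estimated correlation) shifted up with 0 genes called (0 adjusted over the list alone). The P450 median turned from 0.16 to -0.17 with distal intestine and pancreas marker means as covariates, so its direction depends on them. The P450 call was lost without gd0 replicate 1 (adjusted p = 0.335), gd0 replicate 2, gd19 replicate 3 (0.0930) or gd19 replicate 6 (0.672), the gd19 array highest in hepatocyte transcripts (8.62, against a gd0 mean of 6.33). It stayed without gd19 replicate 4 (0.0279), the next highest (8.42). The cell cycle call was lost without gd19 replicate 2 (0.0861) or 4 (0.0615). The glucuronosyltransferase call ended without gd0 replicate 4 (adjusted p = 0.206) or gd19 replicate 2 (0.167), and the immediate early call without gd0 replicate 2 (0.0594). The other 19 lists, transporters, glutathione and sulfotransferases, nutrient absorption, iron and calcium handling, interferon, matrix, blood and epithelial cell type markers among them, had 0 genes called over all genes and no list call. Adjusted over the list alone, sulfotransferases, efflux transporters and interferon-stimulated genes had 1 lower each, other enzymes 1 higher and the rest 0.

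**Figure D4:**
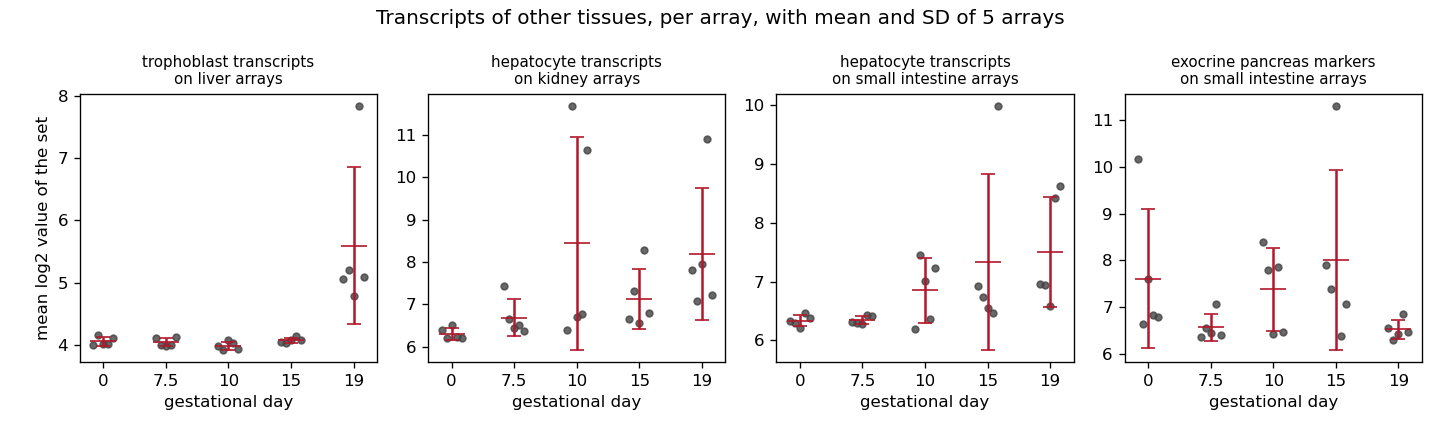
Mean log2 value of transcripts of another tissue on each array by gestational day, with trophoblast transcripts on liver arrays, hepatocyte transcripts on kidney and on intestine arrays, and exocrine pancreas markers on intestine arrays. A point is an array; trophoblast transcripts reached 7.83 on a gd19 liver array and hepatocyte transcripts 11.67 on a gd10 kidney array.

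Counts of changed intestinal genes were 15 of 14507 at gd19 (5 higher, 10 lower), 188 at gd15 (29 and 159, but 117 and 68 without 3 arrays high in pancreas or liver transcripts), 18 at gd10 (6 and 12) and 0 at gd7.5. The limma count of 0 at gd7.5 goes with 798 genes below an unadjusted p of 0.05. Other fits called 1 gene with array weights, 2 with only the arrays of the 2 days, 11 with all 90 arrays and 0 with a plain two-sample test. At gd10 Flvcr2, a membrane transporter, rose by 1.65 ± 0.28 and the cyclin-like Ccnjl by 0.83 ± 0.13, while the clock repressor Ciart (-1.39 ± 0.23) and Bcl6 (-1.28 ± 0.21) fell. At gd15 Flvcr2 (1.25 ± 0.28) and the chemokine Cxcl11 (0.95 ± 0.20) rose and Bcl6 (-1.41 ± 0.21) and Ciart (-1.25 ± 0.23) fell. Circadian genes fell in 4 of 16 cases at gd10 (10 down and 1 up adjusted over the list alone; adjusted p = 1.03e-06; adjusted p = 0.166 with an estimated correlation). At gd15 they fell in 7 cases (11 down and 1 up adjusted over the list alone; adjusted p = 2.09e-09; adjusted p = 0.166 with an estimated correlation). Hepatocyte transcripts averaged 7.51 ± 0.94 on the gd19 arrays against 6.33 ± 0.09 at gd0, and reached 9.99 on a gd15 array. Exocrine pancreas markers averaged 6.52 ± 0.20 at gd19, 8.01 ± 1.92 at gd15 and 7.60 ± 1.49 at gd0.

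All 10 genes named for the gd19 intestine lost their call without single arrays, and the gd19 count ran from 0 without gd0 replicate 5 (1227 genes below an unadjusted p of 0.05 with all arrays) to 18 without gd19 replicate 2. The gd15 count ran from 19 without gd0 replicate 6 to 361 without gd15 replicate 2, and the gd10 count from 10 without gd10 replicate 1 to 28 without gd19 replicate 2. At gd15 the share of higher genes was 15.4% as deposited, 35.8% after quantile normalization and 32.2% after centring, and it turned to 63.2% (117 higher, 68 lower) without the 3 arrays high in pancreas or liver transcripts. The shares at gd19 were 33.3%, 60% and 75% as deposited, after quantile normalization and after centring, and at gd10 33.3%, 50% and 57.1%.

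In the placenta between gd10 and gd19, 16 of 20 pregnancy-specific glycoprotein and related Ceacam genes rose and 2 fell (16 and 3 adjusted over the list alone), and the list call was lost with an estimated correlation (adjusted p = 0.494). The gd10 signals of the next 6 genes lay below the dim level of the arrays, so each fold is a lower bound. Ceacam14 was at least 83.2-fold higher (7.97 ± 0.38, SE, n = 5; adjusted p = 1.08e-08), Ceacam12 at least 85.3-fold (7.95 ± 0.23), Ceacam5 at least 44.9-fold (7.54 ± 0.52) and Psg16 at least 49.3-fold (7.17 ± 0.40). The prolactin-family gene Prl8a8 rose at least 84.4-fold (7.48 ± 0.27) and the placental cathepsin Ctsq at least 114-fold (7.14 ± 0.47). Named among the falls were Dio3, which inactivates thyroid hormone, 23.3-fold lower (-4.54 ± 0.44), the carotene oxygenase Bco1 (-4.46 ± 0.37) and neuromedin U (Nmu, -4.34 ± 0.44). The rule also gave the peptidase inhibitor Pi15 (-4.16 ± 0.63), and the cathepsin Cts7 and the copper oxidase Hephl1, at least 6.45-fold and at least 16.9-fold lower (-4.24 ± 0.51 and -4.18 ± 0.32 to signals below the dim level). Genes of the Psg, prolactin and cathepsin families have near-identical paralogs, so probes of the array can read several of them.

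**Figure D5:**
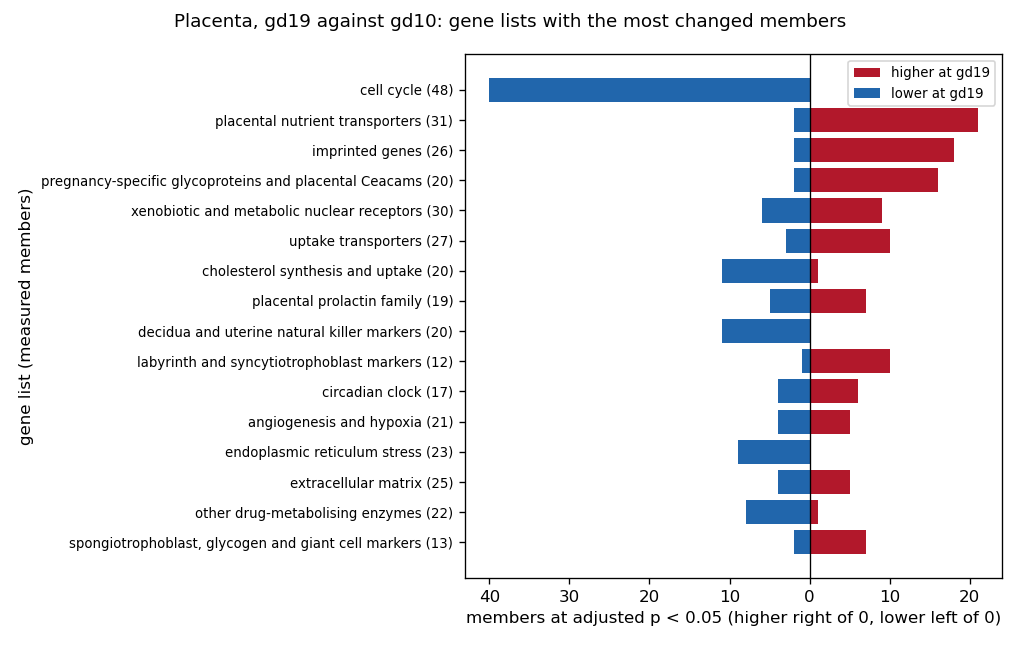
Number of genes of each of 16 lists that were higher or lower in the placenta at gd19 than at gd10 at an adjusted p under 0.05 over all genes tested, with the number of measured members in brackets. Bars start at 0; in the cell cycle list 40 of 48 genes were lower and 0 higher, and among the nutrient transporters 21 of 31 were higher and 2 lower.

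Proliferation genes fell in the placenta. Of 48 cell cycle genes 40 were lower at gd19 and 0 higher (43 and 0 adjusted over the list alone; median -0.94, adjusted p = 2.15e-11; adjusted p = 0.596 with an estimated correlation). The largest changes in the list were Rrm2 (-2.01 ± 0.51), Ccna2 (-1.93 ± 0.35) and Top2a (-1.87 ± 0.32). Cholesterol synthesis had 11 of 20 lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 6.89e-05; adjusted p = 0.494 with an estimated correlation), among them Dhcr7 (-1.86 ± 0.20) and Idi1 (-1.83 ± 0.19). Decidua and uterine natural killer markers had 11 of 20 lower and 0 higher (12 and 1 adjusted over the list alone; median -1.89, adjusted p = 0.000172; adjusted p = 0.596 with an estimated correlation). Among them were the decidual regulators Bmp2 (-3.47 ± 0.23) and Hand2 (-2.82 ± 0.31) and granzyme B (Gzmb, -2.83 ± 0.83). The mean of these maternal markers was 10.16 ± 0.82 at gd10, 9.09 ± 0.64 at gd15 and 8.58 ± 0.66 at gd19. Steroid genes had 6 of 10 lower and 2 higher (7 and 2 adjusted over the list alone) without a list call (adjusted p = 0.0718), with the cholesterol carrier Star 8.56-fold (-3.10 ± 0.25) and the hydroxysteroid dehydrogenase Hsd3b6 10.1-fold lower (-3.34 ± 0.55). B, plasma and T cell markers had 4 of 7 lower (5 adjusted over the list alone; adjusted p = 0.0214; adjusted p = 0.494 with an estimated correlation). Endoplasmic reticulum stress had 9 of 23 lower (9 adjusted over the list alone; adjusted p = 0.0121; adjusted p = 0.693 with an estimated correlation; 0.0813 without placenta gd10 replicate 4).

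Rises outnumbered falls in the transport and trophoblast lists, but none of these lists held with an estimated correlation. Of 31 nutrient transporters 21 were higher and 2 lower (22 and 2 adjusted over the list alone; median 1.23, adjusted p = 1.51e-05; adjusted p = 0.525 with an estimated correlation). The risers included the iron exporter Slc40a1 (3.99 ± 0.33), calcium-binding S100g (3.16 ± 0.48), the fatty acid binder Fabp3 (2.92 ± 0.35) and the glucose carrier Slc2a1 (1.33 ± 0.24). Labyrinth and syncytiotrophoblast markers had 10 of 12 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.00198; adjusted p = 0.525 with an estimated correlation), with Slc16a3 up by 2.07 ± 0.24. Imprinted genes had 18 of 26 higher and 2 lower (18 and 3 adjusted over the list alone; adjusted p = 6.89e-05; adjusted p = 0.494 with an estimated correlation), led by Zim1 (4.49 ± 0.35), Dlk1 (3.16 ± 0.24) and Peg3 (2.97 ± 0.28). Of 20 Psg and Ceacam genes 16 rose and 2 fell (16 and 3 adjusted over the list alone; median 5.62, adjusted p = 1.78e-09; adjusted p = 0.494 with an estimated correlation). Cathepsins had 4 higher and 1 lower of 5 (4 and 1 adjusted over the list alone; adjusted p = 0.0459; adjusted p = 0.596 with an estimated correlation; 0.0935 without gd10 replicate 4, 0.0516 without gd15 replicate 3 and 0.0612 without gd19 replicate 5). The prolactin family split into 7 higher and 5 lower of 19 (8 and 5 adjusted over the list alone), without a list call (adjusted p = 0.506). Spongiotrophoblast and giant cell markers split into 7 and 2 of 13 (7 and 2 adjusted over the list alone; Tpbpb 5.42 ± 0.46), also without one (adjusted p = 0.0559). Macrophage markers had 6 of 9 higher (7 adjusted over the list alone; adjusted p = 0.0465; adjusted p = 0.596 with an estimated correlation). This call ended without gd10 replicate 1 (0.0665), gd10 replicate 3 (0.0681), gd19 replicate 5 (0.0626) or gd19 replicate 1 (0.112).

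For drug handling in the placenta, Cyp2s1 was 9.98-fold higher at gd19 (3.32 ± 0.17), while 3 of the 13 P450s fell, Cyp2b10 (-2.00 ± 0.57) and Cyp4b1 (-0.50 ± 0.13) among them (1 up and 3 down adjusted over the list alone). The efflux pumps Abcb1a and Abcb1b rose by 1.76 ± 0.29 and 2.04 ± 0.31 and Abcc3 by 0.59 ± 0.15, with 7 higher and 1 lower, Abcc5 (-1.57 ± 0.27), of 17 efflux transporters (7 and 1 adjusted over the list alone). Abcg2 (0.32 ± 0.40, adjusted p = 0.546) and the prostaglandin carrier Slco2a1 (0.42 ± 0.18, adjusted p = 0.0755) did not pass. Uptake transporters had 10 higher and 3 lower of 27 (10 and 3 adjusted over the list alone), with the thiamine carrier Slc19a2 higher (1.94 ± 0.23) and the nucleoside carrier Slc29a1 lower (-1.48 ± 0.30). Nuclear receptors had 9 higher and 6 lower of 30 (9 and 6 adjusted over the list alone), with Pparg (2.40 ± 0.58) and Rxra (1.63 ± 0.23) higher. Other enzymes had 8 lower and 1 higher of 22, glutathione transferases 2 and 4 of 20, and sulfotransferases 2 and 2 of 7, with the same counts adjusted over the list alone, and no drug-handling list passed as a list. The 11 lists not yet given had between 0 and 8 genes higher and between 0 and 4 lower, without list calls. Interferon-stimulated genes (8 of 21 higher), iron handling (6 higher, 1 lower of 22), matrix (5 and 4 of 25), circadian (6 and 4 of 17) and angiogenesis genes (5 and 4 of 21) were among them. So were immediate early (4 higher of 17), yolk sac and embryonic blood (3 and 3 of 15), erythroid (3 higher of 8) and neutrophil markers (2 and 2 of 8). Adjusted over the list alone, angiogenesis genes had 5 and 5, immediate early genes 3 higher, yolk sac and embryonic blood markers 4 and 3 and smooth muscle markers 0, where 1 was lower over all genes, and the others kept their counts.

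In total 5696 of 14421 placental genes differed between gd10 and gd19, 3234 higher and 2462 lower, 3285 of them by at least 1.5-fold. Over all genes tested the arrays of the 2 days did not overlap for 3489 (24.2%; 0.794% by chance). The gd10 arrays differed in tissue content, with smooth muscle markers at 10.09 and 10.48 on replicates 1 and 4 and between 8.36 and 8.48 on the other 3, and the count was 5420 without replicate 1 and 5449 without replicate 4. With each array left out it ran from 4965 without gd19 replicate 4 to 6944 without gd19 replicate 1, the array that stood apart from its group (mean r 0.930). Between gd10 and gd15 5566 genes differed (3223 higher, 2343 lower), with Ceacam14 at least 114-fold and Ceacam5 at least 68.7-fold higher, and Nmu at least 33.8-fold and the placental lactogen gene Prl3d3 35.3-fold lower. Centring each array on its median moved the share of higher genes from 56.8% to 45.4% at gd19 and from 57.9% to 42.7% at gd15 against gd10, and put the median change of all genes at gd15 at -0.11, where it was 0.02 as deposited.

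Between gd15 and gd19 43 genes differed (19 higher, 24 lower), among them the amine oxidase gene Doxl1 (2.89 ± 0.48) and Ly6g6c (2.38 ± 0.34), which rose, and the embryonic globins Hbb-y (-3.63 ± 0.45) and Hba-x (-2.54 ± 0.45), which fell. Cell cycle genes shifted down as a list over this interval (median -0.60, adjusted p = 7.79e-24; adjusted p = 0.494 with an estimated correlation), with 0 of 48 passing limma over all genes and 30 adjusted over the list alone. Yolk sac and embryonic blood markers averaged 10.23 ± 0.65 at gd15 and 9.13 ± 1.22 at gd19 (11.31 on gd19 replicate 1). Whether a change in blood or yolk sac content carries the globin and cell cycle falls was not tested. The share of higher genes was 44.2%, 51.9% after quantile normalization and 56.3% after centring. This count ran from 12 without placenta gd15 replicate 1 to 173 without gd19 replicate 1, and was 0 with a plain two-sample test at 1628 genes below an unadjusted p of 0.05, 930 with array weights and 1806 with all 90 arrays.

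The gd19 change itself was compared between the maternal tissues by an interaction term. It differed between liver and kidney for 645 of 13654 genes, 241 with the higher change in liver and 404 with the lower. Cyp4a12a changed by -2.66 in liver and 0.23 in kidney (difference -2.89 ± 0.28, adjusted p = 9.83e-12) and the organic anion carrier gene Slc22a29 by -1.30 and 0.65 (difference -1.95 ± 0.20). The Cyp4a12a signal of the gd19 liver and the Cyp17a1 signal of the gd0 kidney lay below the dim level, so the differences of these genes are not exact. Hdc (0.16 in liver, 2.69 in kidney; difference -2.54 ± 0.34), C7 (-0.20 and 1.55; difference -1.74 ± 0.24), Gpx3 (2.76 and 0.04; difference 2.72 ± 0.39) and Cyp17a1 (3.37 and 0.39; difference 2.98 ± 0.45) differed as well. Between liver and small intestine 442 of 13632 genes differed (233 and 209), with Cyp17a1 (difference 3.50 ± 0.45), Gpx3 (2.59 ± 0.39) and Slc31a1 (-0.64 ± 0.10) among them. Between kidney and small intestine 35 of 13587 differed (18 and 17), with Hdc (difference 2.64 ± 0.34), C7 (1.55 ± 0.24) and Slc25a43 (-0.96 ± 0.14) among them, a count of 19 without kidney gd19 replicate 4 and 143 with array weights. As lists, P450s (adjusted p = 0.000987; adjusted p = 0.768 with an estimated correlation), cholesterol synthesis (9.34e-08; adjusted p = 0.742 with an estimated correlation) and glucose metabolism (3.14e-05; adjusted p = 0.482 with an estimated correlation) had the lower change in liver than in kidney. The kidney P450 median behind the first of these was 0.02 with the hepatocyte and adipose covariates. Liver had the lower change than small intestine for cholesterol synthesis (4.52e-07; adjusted p = 0.815 with an estimated correlation) and for B, plasma and T cell markers (1.94e-05; adjusted p = 0.815 with an estimated correlation). Kidney had the higher change than small intestine for glucuronosyltransferases (0.00262; adjusted p = 0.415 with an estimated correlation) and the lower for B, plasma and T cell markers (0.00224; adjusted p = 0.444 with an estimated correlation).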

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

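The tests of explanations in this part and the sets of marker genes of other tissues were chosen after the results were seen, and the rule for the kidney P450s was made stricter after its first result. A sample was singled out when its gap to the nearest of its group was over 0.71 of the group's range. Of 82 groups tested for array correlation or a marker mean, 13 passed this limit, and of 1135 groups of values of named genes 111 did (9.78%, where chance gives 5%).

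Array correlation put kidney gd0 replicate 6 (mean r with its group 0.9952) and placenta gd19 replicate 1 (0.930) apart. Trophoblast transcripts reached 7.83 on liver gd19 replicate 4, where the other 4 arrays lay between 4.78 and 5.21. Hepatocyte transcripts stood at 10.89 on kidney gd19 replicate 5 (others 7.09 to 7.96), at 7.44 on kidney gd7.5 replicate 1 and at 9.99 on small intestine gd15 replicate 5. Adipose markers stood at 10.45 on kidney gd15 replicate 5. Exocrine pancreas markers stood at 10.18 on small intestine gd0 replicate 1 and at 6.05 on liver gd10 replicate 6. Transcripts of the proximal intestine were low on small intestine gd10 replicate 4 (9.66) and gd19 replicate 2 (7.48). Placenta gd19 replicate 1 was high in yolk sac and embryonic blood markers (11.31), and placenta gd10 replicate 4 was low in decidua markers (8.74).

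The gd19 change differed between tissues, by the interaction term, for 645 genes between liver and kidney, 442 between liver and small intestine and 35 between kidney and small intestine. Of 100 splits of the arrays, 1, 6 and 8 gave as many genes, with 305, 1336 and 523 as the highest other counts. The splits mix gd19 and gd0 within each tissue, which also takes away a day effect that both tissues share. They ask whether there is any day effect, not whether it differs, so they do not set these differences apart from chance. For the last 2 counts, splits that call several times more genes point to a structure among the samples.

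Features with several symbols or none, 13767 in all, were outside the comparisons. Of those tested, 156 changed in liver at gd19 (61 higher, 95 lower of 7835), 28 in kidney (14 and 14 of 7704), 3 in small intestine (1 and 2 of 8060) and 2159 in placenta between gd10 and gd19 (850 and 1309 of 7716).

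Placental transcripts appeared on the gd19 liver arrays. Of 37 other genes abundant in placenta and near the floor in liver, 62.2% stood on average above all 20 earlier liver arrays at gd19 (56.9% to 100% with other limits), against at most 8.11% at an earlier day. The earlier share is held down by the choice of genes, which had to lie under 6 on all 20 earlier arrays but not at gd19, so it is no fair background. At gd19 the share was 94.6% on replicate 4 alone and 35.1% without it, so placental RNA is a candidate explanation chiefly for that array and weaker for the other 4. Its amount is not given, because signals of different tissues are not on a common scale and the trophoblast mean lay below the dim level on 4 of the 5 arrays. At gd15 Phlda2 rose by 1.20 ± 0.13 and Peg3 by 2.53 ± 0.27, genes chosen after their values were seen, while the trophoblast mean moved by 0.02 ± 0.04. This argues against placental RNA for their gd15 rise only as far as the trophoblast mean can show it. That mean lay below the dim level at both days (4.06 at gd0 and 4.08 at gd15, against 5.78 and 5.79), where a small amount may not show. Whether placental RNA adds to the gd19 signals of Peg3 and Phlda2 was not tested. Peg10, chosen likewise, and Prl8a2 stay open, as does expression by liver cells at gestation, which was not tested: at gd15 they moved by -0.0224 (SE 0.31) and 0.0755 (SE 0.40) between signals below the dim level, which decides nothing.

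Liver transcripts appeared on the kidney arrays. All of 42 other liver-abundant genes (100%) stood on average above all gd0 kidney arrays at gd19, and 57.1% did at gd7.5, so liver RNA in the kidney samples is a candidate explanation. The genes had to lie under 6 on all gd0 kidney arrays but not later, so the choice holds the gd0 level down. The gd19 average includes replicate 5 (10.89 in hepatocyte transcripts), and the share without it was not computed. The covariates argue against it for the rise of fatty acid oxidation genes, whose median was 0.20 as reported and 0.21 with hepatocyte and adipose covariates. It was 0.21 without the 3 kidney arrays highest in liver transcripts. The list was called each time with the preset correlation, but not as reported with an estimated correlation. For the P450s liver RNA cannot be told apart from a renal change. Their median was 0.02 with the covariates (adjusted p = 0.718) and 0.28 without the 3 arrays (adjusted p = 4.53e-07), over alternatives from 4.44e-08 to 0.718. Of the gd19 arrays the omission takes away only replicate 5. The others (7.09 to 7.96 in hepatocyte transcripts) still lay above the gd0 arrays (6.20 to 6.51), so the omission cannot test liver RNA in them.

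Clock genes that peak with the Per genes tended to be lower after gd0, but no clock set passed adjustment over the 36 tests. Genes that peak with the Per genes were lower at gd19 in kidney and small intestine (-0.48 each, exact permutation p = 0.0159, two-sided, 10 of 10 genes) and in liver at gd10 (-0.47, exact p = 0.0238, 10 of 10) more than at gd19 (-0.10, exact p = 0.524). Another clock time of collection at gd0 would raise the opposite-phase genes that peak with Bmal1, as in small intestine at gd10 (0.27, exact p = 0.00794), but at gd19 their exact p was 0.0556 in liver, where they fell (-0.43), 0.254 in kidney (0.16) and 0.151 in small intestine (0.09). Lower glucocorticoid signalling would lower 12 induced genes, as at gd10 in small intestine (-0.57, exact p = 0.0159, 12 of 12) and kidney (-0.41, exact p = 0.0238) and at gd15 in both (exact p = 0.0476 and 0.0397), but at gd19 the exact p was 0.929 in liver, 1 in kidney and 0.389 in small intestine. Neither can be told apart from an effect of gestation, since the labels give no time of day and 5 arrays against 5 allow no exact p below 0.00794, which largely sets the lowest adjusted p over the 36 tests of all days (0.0714).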

How the results depend on the processing

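The alternatives that use marker means as covariates or leave out arrays chosen by their markers were added after seeing the data, and the others were set before. Among 287 values of named genes and 118 of lists, 9 changed direction while past the threshold as reported or under the alternative, of which 8 are lists under covariates. Changes of sign in values that passed neither way were not counted. With hepatocyte and adipose covariates in kidney the P450 median went to 0.0171, with the direction of its list test turned down and no call (adjusted p = 0.718), and that of the other enzymes to -0.0568 (adjusted p = 0.0132). With distal intestine and pancreas covariates in small intestine, P450s went to -0.167, glutathione transferases to -0.169, other enzymes to -0.142, cholesterol synthesis to 0.153, Paneth and goblet markers to 0.106 and pancreas markers to 0.0280. The pancreas value says nothing, because the mean of the same markers was the covariate. With array weights Abcg2 in placenta went to -0.48. Unless the alternative uses fewer samples or genes, the cause was not tested.

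Array weights gave 79 genes in liver at gd7.5 and 3173 at gd10, 286, 1755 and 1511 in kidney at gd7.5, gd15 and gd19, and 1, 184 and 34 in small intestine at gd7.5, gd10 and gd19. In placenta they gave 8574 at gd15 against gd10 and 930 at gd19 against gd15, and for the tissue differences 1482 (liver and kidney) and 143 (kidney and intestine). With only the arrays of the 2 days, which uses fewer samples, the counts were 11 in liver at gd7.5, 37, 138 and 979 in kidney at gd7.5, gd10 and gd15, 2, 1 and 1 in small intestine at gd7.5, gd15 and gd19, and 3 in placenta at gd19 against gd15, and with only the 4 groups 185 for liver and intestine. A plain two-sample test gave 0 genes in liver at gd7.5 and 510 at gd19, 0, 42 and 327 in kidney at gd7.5, gd10 and gd19, 5, 1 and 2 in small intestine at gd10, gd15 and gd19, 0 in placenta at gd19 against gd15, and 124 and 15 for liver and intestine and for kidney and intestine. All 90 arrays in a single fit gave 256 and 829 genes in liver at gd7.5 and gd19, with 6 lists, and 40, 106, 171 and 149 in kidney at the 4 days. The same fit gave 11, 71, 359 and 57 in small intestine and 1806 in placenta at gd19 against gd15.

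Without the arrays whose title ends in an extra number, the counts were 20 in liver at gd7.5, 271 in kidney at gd19, 91 in small intestine at gd15 and 4 in placenta at gd19 against gd15. A minimum change of 1.5-fold left 26, 343, 590 and 293 genes in liver, 33, 57, 100 and 79 in kidney, 37 and 5 in small intestine at gd15 and gd19, 3100 and 3285 in placenta at gd15 and gd19 against gd10, and 261 and 192 for the differences of liver from kidney and from intestine. No filter gave 107 and 2 in small intestine at gd15 and gd19 and 53 for kidney and intestine, where a 50th percentile filter gave 21. Median centring gave 118 and 4 in small intestine at gd15 and gd19 and 71 in placenta at gd19 against gd15, and quantile normalization 5 in small intestine at gd19. The covariates gave 375 genes in liver at gd19 (trophoblast), 119 and 230 in kidney at gd10 and gd19 with 5 lists, and 436 and 4 in small intestine at gd15 and gd19. Without the 3 kidney arrays high in liver transcripts 93 genes were called at gd10, and without 2 placenta arrays 222 at gd19 against gd15. With an estimated correlation 1 list was called in liver, 1 in kidney, 0 in small intestine and 0 in placenta, against 11, 8, 10 and 11 with the preset correlation, and fry called 2 in small intestine and 22 in placenta.

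With the replicate number as a block (replicate block), the counts were 91, 404 and 235 in kidney at gd7.5, gd15 and gd19, 11, 70 and 0 in small intestine at gd10, gd15 and gd19, and 28 in placenta at gd19 against gd15. For the differences between tissues a random block of day and number, at a correlation of 0.031 or 0.032, gave 702, 486 and 37 genes. The labels do not say what the numbers share, and not every pair of arrays correlated above 0.1, so the numbers were not taken as pairs. Within a tissue the mean correlation of residuals between arrays of the same number was -0.006 in liver, -0.049 in kidney, 0.110 in small intestine and -0.056 in placenta, and 4, 1 and 8 of 25 and 1 of 15 arrays correlated best with their own number. Between tissues of the same day it was higher for the same number than for others: 0.072 against -0.016 for liver and kidney (9 of 23 pairs above 0.1), 0.050 against -0.009 for liver and intestine (9 of 22) and 0.044 against -0.011 for kidney and intestine (8 of 21). This is a hint from the data, not the design.

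With each array left out in turn, the counts ran from 16 to 490 in liver at gd7.5, 711 to 2103 at gd10 and 825 to 1385 at gd19, with 7 to 13 lists. In kidney they ran from 48 to 252, 98 to 250, 321 to 689 and 217 to 703 at the 4 days. In small intestine they ran from 0 to 2, 10 to 28, 19 to 361 and 0 to 18, in placenta at gd19 against gd15 from 12 to 173, and for kidney and intestine from 19 to 52. Of 73 called named genes in liver 58 kept the call with each array left out, in kidney 18 of 46, in small intestine 0 of 10 and in placenta 91 of 98. Of the named genes, 61 lost their call with all 90 arrays, 55 with the block, 55 without the arrays of extra number, 37 with only the 2 days, 29 without a filter, 14 with median centring, 11 with quantile normalization and 4 with array weights. Within single tissues, 35 of 90 values lost their call in liver with the trophoblast covariate, 29 of 63 in kidney with its covariates and 16 of 63 without the 3 arrays, 7 of 26 in small intestine with its covariates and 2 of 26 without 3 arrays, and 5 of 108 in placenta without 2 arrays. The trophoblast mean nearly separates gd19 from gd0 in liver, so losses there can also come from lost precision. The balance of higher and lower genes turned in 1, 1, 0 and 1 of 14 alternatives in liver at the 4 days, in 3, 4, 2 and 6 of 15 in kidney, in 4, 2 and 5 of 15 in small intestine at gd10, gd15 and gd19, and in 2, 2 and 5 of 14 in placenta (gd15 and gd19 against gd10, gd19 against gd15). Among them were 117 higher and 68 lower in small intestine at gd15 without 3 arrays, and 145 and 77 in placenta at gd19 against gd15 without 2 arrays. Of the lists, 38 lost their call with an estimated correlation, and 0 changed with the intensity trend. Dim genes are limited by the background, which the filter addresses.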

Other observations

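The splits in this part were run after the counts were seen, and the genes below, apart from those the naming rule gives, were chosen after their values were seen. Of 100 splits of the arrays of a comparison, the real one included, 1 gave as many genes as the real split in liver at gd10 (1391; highest other 69), gd15 (2345; 1341) and gd19 (1250; 412). The same number, 1, was found in kidney at gd7.5 (139; 28), gd15 (611; 2) and gd19 (604; 4), in small intestine at gd10 (18; 3) and gd19 (15; 0), and in placenta at gd15 (5566; 353) and gd19 (5696; 3817) against gd10 and gd19 against gd15 (43; 18). In liver at gd7.5 3 splits did (51; 106), in kidney at gd10 2 (217; 403) and in small intestine at gd15 3 (188; 1789). Each of these counts was reached by under 5 of 100 splits, taken alone and without adjustment over the 15 comparisons. A chance split is unlikely for each but not excluded, and the last 3 are the least firm, as other splits exceeded them. In small intestine at gd7.5 all 100 splits gave at least the count of 0, as any split must, so they decide nothing there. The split with 1789 genes points to a structure among the intestine samples. Gut segment transcripts differed within days. Distal intestine transcripts stood at 10.69 or above on gd0 replicates 1 and 2, gd15 replicates 2 and 5 and gd19 replicate 2. Elsewhere they reached at most 10.33. Proximal ones stood at 9.15 or below on these arrays and at 9.66 or above on the others. Whether this made the 1789 was not tested. With distal intestine and pancreas covariates 436 genes were called at gd15 and 4 at gd19 (188 and 15 as reported).

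Counts of gene lists are not set apart from chance. Adjusted over the comparison alone, the real split called 10 lists in liver, 8 in kidney, 10 in small intestine and 12 in placenta, and 19, 21, 50 and 18 of 100 splits called as many, with up to 16, 12, 18 and 15 lists.

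Cish and Socs2, feedback inhibitors that STAT5 induces, were higher than at gd0 at each later day in liver and kidney. Cish rose in liver by 1.56 at gd7.5, 1.36 at gd10, 1.61 at gd15 and 1.33 at gd19 (SE 0.26), and at gd19 by 0.85 ± 0.15 in kidney and 0.55 ± 0.11 in small intestine. Socs2 rose at gd10 by 1.58 ± 0.23 in liver and 1.13 ± 0.13 in kidney, and in small intestine at gd19 it did not pass (0.44 ± 0.12, adjusted p = 0.214). Bcl6, which STAT5 represses, fell by 0.95 ± 0.16 in liver, 0.95 ± 0.19 in kidney and 1.06 ± 0.21 in small intestine at gd19. In small intestine the naming rule did not give Bcl6 at gd19, so it either was not called or its arrays overlapped. No test of the hormone behind these changes was run.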
